A study of Zea mays with 7 samples.

How the data were processed

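Short 3′ cDNA tags were sequenced from 2 mm maize ears of wild-type B73 and of the ramosa3 (ra3) mutant. Per the labels' protocols, cDNA made on oligo(dT) beads was cut with DpnII or NlaIII, a tag beside the site was released with MmeI, and the tag libraries of both enzymes from an ear pool shared 1 lane. Each genotype had 3 biological replicates, each a pool of 4 to 5 ears per the labels, and ra3 replicate 3 had another lane (3b) described as a technical replicate.

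Per the file headers, each lane's table gives for every distinct 20-base tag a raw count and a scaled value (PPM). The raw count is the number of reads of that tag in whole numbers, not normalized by the authors. The deposited PPM value was treated as a score, because it is rounded to whole numbers and the total it implies is below the sum of the raw counts in each lane. It was not used in any test. The software, quality filter and any correction of sequencing errors behind the tag tables are not given in the sources used here. A pair of further deposited tables by the authors lists genome positions for 216193 of the 791848 distinct tags. No tag there has more than 3 positions, 188750 tags have 1 position, and both tables hold the same 249944 positions. The aligner settings and the genome build are not given in the sources used here, so coordinates stand as the authors' files give them. An end coordinate lies 20 bases after the start.

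Tags were read by their first bases as DpnII or NlaIII tags. Reads with another start made up 0.0339% to 0.0396% of a lane and were left out. Neither a genome nor transcripts were used here, so tags could not be tied to genes. In the place of genes, uniquely placed tags on the same strand were chained while the next start lay within 1000 bp, which gave 58443 loci with a median of 2 distinct tags. A locus is therefore a stretch of placed tags, with no gene name, exon or untranslated region attached. The transcript level of ra3, the fixed gene lists, the antisense share and the windows around the ra3 locus need gene positions in the authors' build and were not analysed here. Of the test around the ra3 locus, the part by chromosome was run. The RefSeq gene table of the assembly Zm-B73-REFERENCE-NAM-5.0 served only to place ra3 on chromosome 7.

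Lanes 3 and 3b were summed and counted as 1 replicate. Loci were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) on raw counts, 3 replicates against 3, with filterByExpr defaults. Because the ratio of DpnII to NlaIII reads varied between lanes, each locus had an offset built from its pooled rate per enzyme and the TMM-scaled depth of that enzyme in each replicate. Tags were tested by sequence in the same way, separately per enzyme, and the p-values of both enzymes were adjusted together. Relative use of the tags within a locus was tested with diffSpliceDGE and Simes p-values. All adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. A standard error was taken as the absolute log2 fold change divided by the square root of the F statistic. Scaled counts (CPM) were taken over DpnII and NlaIII reads together for loci. A fold against a genotype with no count is a lower bound, the mean CPM of the other genotype over the CPM of 3 counts in all replicates of that genotype. Where a genotype had 1 to 3 counts, the ratio is given with an exact 95% Poisson interval. Such bounds and intervals cover counting error only.

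The named loci followed a rule fixed before the data were examined: the 12 highest and 12 lowest log2 fold changes among loci past the threshold with a mean of at least 10 CPM and no overlap between the replicates of the genotypes, or all that pass where fewer do. The part of the rule that asks for an informative product name, and the listed genes, could not be applied without gene names. A tag was called ra3-only when it had at least 5 counts in each ra3 replicate, at least 30 in all, and a wild-type total of at most 2% of its ra3 total. Wild-type-only tags had the mirrored criteria. A partner of a ra3-only tag was a uniquely placed tag of the same enzyme with at least 15 wild-type counts that differed from it by 1 base after the enzyme site; the most abundant one in wild type was taken. Partner loci less than 5 Mb apart were joined, and a group of at least 3 loci was called a segment. The criteria for ra3-only tags, partners and segments were chosen after the data had been seen.

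The replicate numbers of the genotypes were checked for pairing before any blocked fit. Over tested loci, the deviations of same-numbered replicates from their genotype means correlated with r = 0.314 for number 1, 0.110 for number 2 and 0.372 for number 3. Since every value lay above 0.1, the numbers were treated as pairing the samples, although the labels name no shared batch. The evidence for pairing was weak. These values came from both enzymes together, whose ratio varied between lanes, and wild-type replicate 2 correlated better with ra3 replicate 1 (r = 0.163). In DpnII tags alone the same numbers gave 0.0440, 0.00351 and 0.129, and in NlaIII tags alone 0.322, 0.0633 and 0.359. A fit with the replicate number as a block was run beside the unblocked design.

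The tests were tried on simulated counts with the real tag means, depths and common spread and 200 changed loci or tags. For loci, 16% of the 2-fold and 82% of the 4-fold changes were recovered among 18701 tested loci, with 0 false calls. For tags, 3% of the 2-fold and 47% of the 4-fold changes were recovered among 45704 tested tags, with 2 false calls. For relative use, 0% of the 2-fold and 5% of the 4-fold changes were recovered among 6349 tests. Of 200 planted 1-base variants, 98% were recovered as ra3-only, and a count of 0 arose among the tags that were not planted. The variants were planted on abundant tags and took all counts of ra3 replicates 2 and 3 and part of those of replicate 1. The tags that were not planted had equal means in both genotypes. These settings made both outcomes likely and do not cover variants with low shares. Alternatives were plain TMM without the enzyme offset, DESeq2 1.42.0, limma voom (limma 3.58.1), other filters, each enzyme alone, each lane of ra3 replicate 3 alone, the replicate block and leaving out each replicate. The alternative with only the 3′-most annotated site was not run. Figures were drawn with matplotlib.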

Results

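Tag counts were compared between young female inflorescences (2 mm ears) of wild-type B73 and ra3 maize. RAMOSA3 is a trehalose phosphate phosphatase, and mutants branch more in the ear and tassel. The wild-type lanes held 3836389, 3962918 and 4019628 reads. The ra3 lanes held 3814018, 3946787, 4146424 and 3943393 reads, the last of them from lane 3b. DpnII tags made up 40% to 47.8% of a lane. Uniquely placed tags took 71.5% to 73.2% of the reads of a lane. The transcript level of ra3 itself was not analysed here, so the genotype labels were not checked against that gene.

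The first question was which transcribed loci differed in level between the genotypes. Among the loci named by the rule, the loss with the largest fold lay on chromosome 6, and 3 others lay near the end of chromosome 7. On chromosome 7, the locus at 160867383 to 160867817 on the minus strand fell from 95 ± 13.1 CPM in wild type to 0.845 ± 0.382 CPM in ra3 (SD, n = 3 each; log2 fold change -6.83, SE 0.29, adjusted p = 6.64e-06, edgeR); with a ra3-only tag 1 base from its own added, the log2 fold change was -2.82. Beside it, the locus at 160964137 to 160964200 fell from 45.9 ± 4.27 to 0.722 ± 0.0907 CPM (log2 fold change -5.85, SE 0.25) and the locus at 160868917 to 160871498 fell from 25.5 ± 1.51 to 1.28 ± 0.767 CPM (log2 fold change -4.52, SE 0.40). The locus at 160867383 had 1122 counts in wild type and 13 in ra3, and without its 3 wild-type-only tags 117 and 12. The locus at 160868917 had 302 counts in wild type and 17 in ra3, and without its 2 wild-type-only tags 56 and 17. The wild-type counts at 160964137 came from the tag GATCGATTGGAACCCCTGGC (542 counts, 0 in ra3). An unplaced ra3-only tag with the same first 16 bases, GATCGATTGGAACCCCCCGG, had 602 counts in ra3 and 0 in wild type, so a changed sequence was not told apart from a lower level there. On chromosome 6, the lost locus at 28419976 to 28420437 had 78.9 ± 8.48 CPM in wild type and 0.0412 ± 0.0714 CPM in ra3. Its counts were 931 in wild type and 1 in ra3, a ratio of 1249 relative to reads (95% interval 224 to 49368). In the opposite direction, the locus at 16935473 to 16935792 of chromosome 6 had no count in wild type and 58.3 ± 23.1 CPM in ra3, at least 230-fold higher. All its 1033 counts came from its 2 ra3-only tags, so a changed sequence was not told apart from a higher level there. On chromosome 8, the locus at 168359186 to 168360637 had no count in wild type and 24.7 ± 12.4 CPM in ra3, at least 97.2-fold higher. It had 444 counts in ra3, and 39 without its 3 ra3-only tags. An unplaced ra3-only tag 1 base from 1 of these had 177 counts in ra3 and 0 in wild type. A changed sequence was thus not told apart from a higher level at 168359186. The locus at 161242611 to 161242705 of the same chromosome rose from 0.249 ± 0.431 to 36.0 ± 3.85 CPM. This was a ratio of 145 (95% interval 49.3 to 705) on 3 counts in wild type, all in replicate 3. All counts of this locus came from its 3 ra3-only tags, and it lay 0.297 Mb from a partner tag. A changed sequence was not told apart from a higher level there either.

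In all, 35 of the 18843 tested loci passed the threshold, 11 higher and 24 lower in ra3, and 1035 had an unadjusted p under 0.05. The rule for named loci gave 18, of which 6 were higher and 12 lower. Apart from the loci above, the higher ones changed by moderate amounts. The locus on chromosome 5 at 2593907 to 2595042 rose from 11 ± 1.42 to 47.2 ± 7.32 CPM (log2 fold change 2.06, SE 0.20), and that on chromosome 6 at 14793306 to 14795310 rose from 5.98 ± 2.03 to 22.6 ± 1.82 CPM. The locus on chromosome 7 at 119275588 to 119276132 rose from 7.13 ± 1.06 to 42.4 ± 20 CPM through 1 ra3-only tag; its other tags had 82 counts in wild type and 54 in ra3. Among the lower ones, chromosome 5 held 4 loci between 186244715 and 191467329, with log2 fold changes from -2.87 to -1.75. For the one at 190887302, a ra3-only tag with the first 16 bases of its main tag had 1468 counts in ra3 and 1 in wild type. Chromosome 2 held 2 such loci, at 182109618 (log2 fold change -2.48) and 175324018 (log2 fold change -2.26). The most abundant named locus, on chromosome 1 at 280962462 to 280963647, fell from 287 ± 14.1 to 87.8 ± 4.50 CPM (log2 fold change -1.75, SE 0.15, adjusted p = 0.00204, edgeR), but was not called once a ra3-only tag 1 base from its own was added (log2 fold change -0.72). The remaining lower locus, on chromosome 7 at 126449005, fell from 21.6 ± 2.94 to 1.64 ± 1.31 CPM, but not once a ra3-only tag 1 base from its own was added (log2 fold change 0.75). All 18 also passed with DESeq2, with the replicate block and without the enzyme offset, 16 with limma voom, and 8, 9 and 9 without wild-type replicates 1, 2 and 3. The count of 35 changed when a replicate was left out. It was 9, 11 and 10 without wild-type replicates 1, 2 and 3, all among the 35. Without ra3 replicates 1, 2 and 3 it was 112, 19 and 206, with 33, 14 and 35 of them among the 35. DESeq2 called 120 loci, and 448 passed without a filter on low counts.

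**Figure D1:**
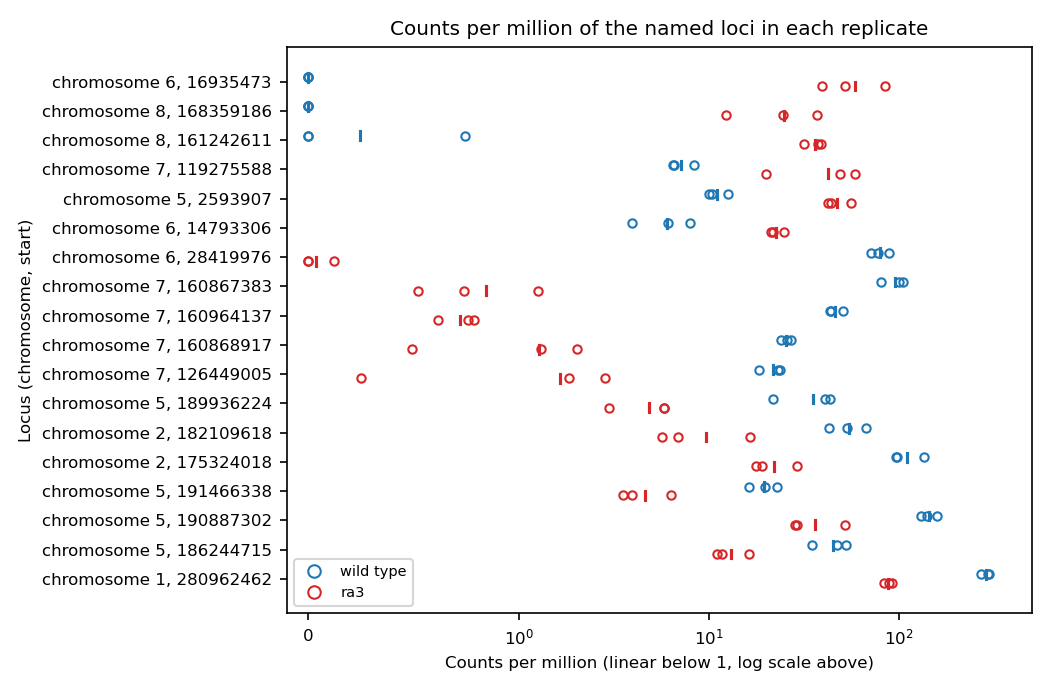
CPM (x axis, linear below 1 and on a log scale above) of the 18 named loci (y axis, chromosome and start) in each replicate; circles are replicates, vertical bars the mean of 3, blue wild type and red ra3. In each locus the genotypes do not overlap, from 0 against 58.3 CPM at the top to 287 against 87.8 CPM at the bottom.

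DpnII and NlaIII tags measure a locus separately from the same RNA. Of the 35 called loci, 19 could be tested with each enzyme alone, and the fold changes had the same sign in 17 of them, which calling on the sum of both enzymes favours. Among the 9403 loci tested with both, DpnII tags called 17, NlaIII tags 8, and 4 were called by each. Across these loci, the log2 fold changes correlated with r = 0.350 (Spearman's rho 0.180); loci are not independent replicates.

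Called loci were then located relative to the chromosome that carries ra3, chromosome 7. There, 11 of 1528 tested loci passed the threshold, 9 of them lower and 2 higher in ra3. The odds ratio against the other chromosomes was 5.22 (95% interval 2.31 to 11.1; Fisher's exact test, two-sided, p = 6.46e-05, adjusted p = 0.000711 over 11 tests). Called loci that lie side by side, as at 160867383, 160867599 and 160868917, are not independent. The interval is therefore likely too narrow and the p-values too small. No other chromosome differed from the rest after adjustment. The lowest p among them was 0.0285 for chromosome 3, where 0 of 2039 loci passed (adjusted p = 0.157). With DpnII tags alone the odds ratio was 2.73 and no longer passed (exact p = 0.0540). It was 15 without ra3 replicate 1, 2.94 without ra3 replicate 3 and 9.06 without wild-type replicate 1.

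Tested by sequence, tags showed a different balance from loci. Of 46345 tested tags, 409 differed, 337 higher and 72 lower in ra3, and 2313 had an unadjusted p under 0.05. Tags with no genome position made up 19.6% of the tested tags and 76.0% of the called ones. Among the 337 tags higher in ra3, 296 had no position (odds ratio 30.6, 95% interval 22.0 to 43.7, Fisher's exact test). Tags of the same transcript are not independent, so this interval is likely too narrow. Of the 72 tags lower in ra3, 52 had 1 position. These lay mainly on chromosome 7 (15 tags), chromosome 5 (14), chromosome 2 (9) and chromosome 6 (7). The number of called tags was 227, 244 and 203 without wild-type replicates 1, 2 and 3, and 701 and 640 without ra3 replicates 1 and 3. It was 637 with a filter of at least 10 counts in total.

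Many tags occurred in ra3 alone. By the criteria given with the processing, 591 tags were ra3-only, of which 540 had no genome position, whereas 23 tags were wild-type-only and 4 of these had no position. In the other 18 ways of setting 3 replicates against the remaining ones, at most 3 tags met the same criteria. Of the 540 tags, 169 (31.3%) had a uniquely placed partner tag 1 base away. Of 540 control tags without a position, matched in mean count, 54 (10%) had such a partner. The partners were lower in ra3 in 161 of 169 pairs, with a median log2 fold change of -2.18 (quartiles -3.20 and -0.88), against 0.05 (quartiles -0.20 and 0.43) for placed tags matched to the partners in wild-type count and -0.10 for the partners of the control tags. The sum of both tags of a pair had a median log2 fold change of 0.19 (quartiles -0.25 and 0.63). The most abundant pair lay on chromosome 7 at 141033776 to 141033796. Its placed tag GATCTCTCGATTTATTTTCA had 1833 CPM of DpnII reads in wild type and 404 in ra3. Its ra3-only tag, with the substitution G9A counted from the first base of the tag, had 4.90 in wild type and 1905 in ra3. On chromosome 1 at 253447762, the placed tag of another pair (C13T) had 352 in wild type and 215 in ra3, and the ra3-only tag had 0.363 and 140.

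The partner tags lay close together in parts of 7 chromosomes. They fell in 149 distinct loci, 69 of them (46.3%) on chromosome 7, where 10000 random draws of as many placed loci gave a median of 12 and at most 26. The fullest 10-Mb window held 21 loci, against at most 11 in the draws (permutation p = 1e-04, the smallest the draws can give). In all, 161 of the 169 pairs fell into 10 segments. The longest ran from 121.8 to 147.8 Mb of chromosome 7 with 44 loci, followed on the same chromosome by one from 153.8 to 161.9 Mb with 21 loci. Others lay at 173.0 to 186.1 Mb of chromosome 2 (17 loci), 182.4 to 195.3 Mb of chromosome 5 (15 loci), 245.6 to 257.0 Mb of chromosome 1 (10 loci), 158.6 to 160.9 Mb of chromosome 8 (10 loci) and 164.5 to 169.1 Mb of chromosome 6 (9 loci).

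**Figure D2:**
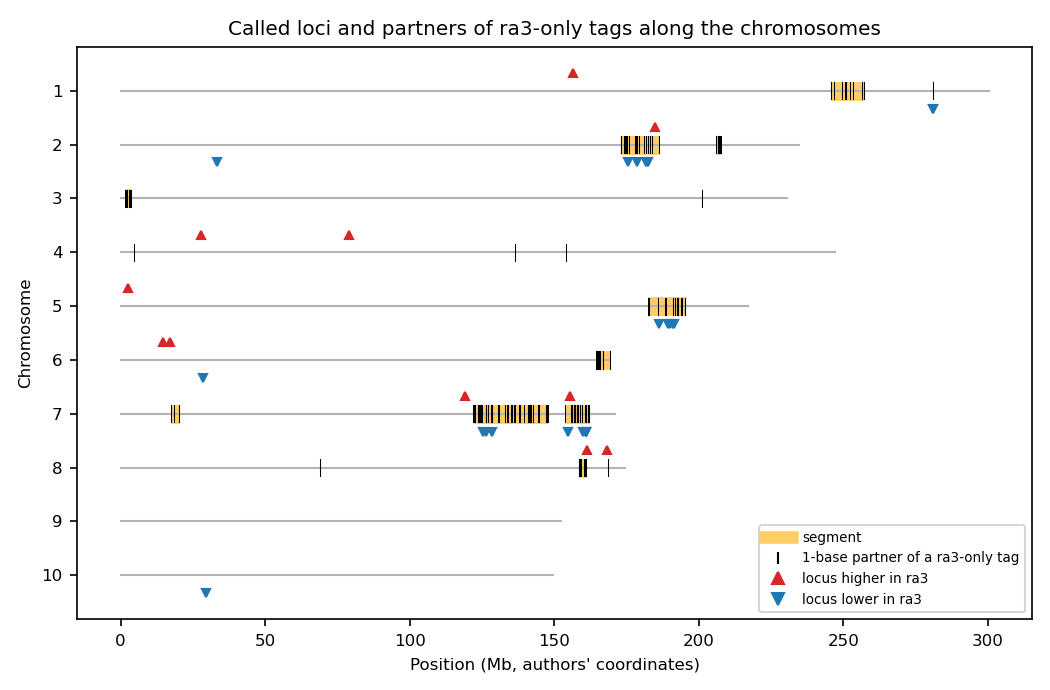
Chromosomes (y axis) drawn to the highest coordinate in the authors' files, with position in Mb on the x axis. Black ticks are partners of ra3-only tags, orange bars the 10 segments, red triangles the 11 loci higher and blue triangles the 24 loci lower in ra3; 19 of the 24 lower loci lie inside segments.

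The loci lower in ra3 lay mostly in these segments. Of the 24, 19 were inside, where 1176 loci were tested, and 5 were outside, where 17667 were tested (odds ratio 57.9, 95% interval 20.9 to 199, Fisher's exact test, two-sided, p = 3.53e-19). Without the loci that hold a partner tag, 14 of 18 lower loci were inside (odds ratio 59.4, 95% interval 18.6 to 249). This does not set aside changed sequences, because a partner differs by 1 base only. The loci at 160964137 and 190887302 stay among the 14, although a ra3-only tag shares the first 16 bases of their main tag. The segments were also drawn from these same libraries. Of the 11 higher loci, 2 were inside (odds ratio 3.34, 95% interval 0.351 to 16.2, exact p = 0.147). Of the 29 uniquely placed tags higher in ra3, 11 were inside (odds ratio 9.07, 95% interval 3.87 to 20.3, exact p = 7.70e-07). Neighbouring loci, and tags of the same transcript, are not independent, so these intervals are likely too narrow and the p-values too small. When the ra3-only tags were added to the loci of their partners, the median log2 fold change of the 147 tested partner loci moved from -0.63 to -0.04. Of the 6 partner loci called lower, 1 was still called after that addition. This was the locus on chromosome 7 at 160867383, whose log2 fold change shrank from -6.83 (SE 0.29) to -2.82 (SE 0.21; adjusted p = 0.000842, edgeR). The locus on chromosome 1 at 280962462 went from -1.75 (SE 0.15) to -0.72 (SE 0.17; adjusted p = 0.318, edgeR) and was no longer called, because its fold change was smaller. The locus on chromosome 7 at 126449005 went from -3.61 (SE 0.47) to 0.75 (SE 0.46).

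Within a pair, the share of the ra3-only tag differed between the ra3 pools, and the order of the pools varied between segments. In the chromosome 7 segment from 121.8 Mb, the median share was 56.2% in replicate 1 (quartiles 38.3% and 73.7%) and 100% in replicates 2 and 3. In the next segment it was 42.5%, 99.4% and 100% in replicates 1, 2 and 3. Near the other end of chromosome 7, at 17.4 to 20.2 Mb, it was 22.8%, 87.4% and 74.8%. On chromosome 1 the order was different, with 50.5%, 26.3% and 37.1%, and on chromosome 8 the shares were 81.7%, 58.0% and 58.5%. Segments accounted for 38.5% of the variance of the share over pairs in replicate 1, 69.2% in replicate 2 and 77.7% in replicate 3 (permutation p = 1e-05 in each, the smallest that 100000 permutations can give). This compares segments within a replicate and does not test the pools against each other. Pairs of the same locus are not independent, so these p-values are likely too small. On chromosome 7, replicate 1 had the lowest share in 96% of 75 pairs.

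**Figure D3:**
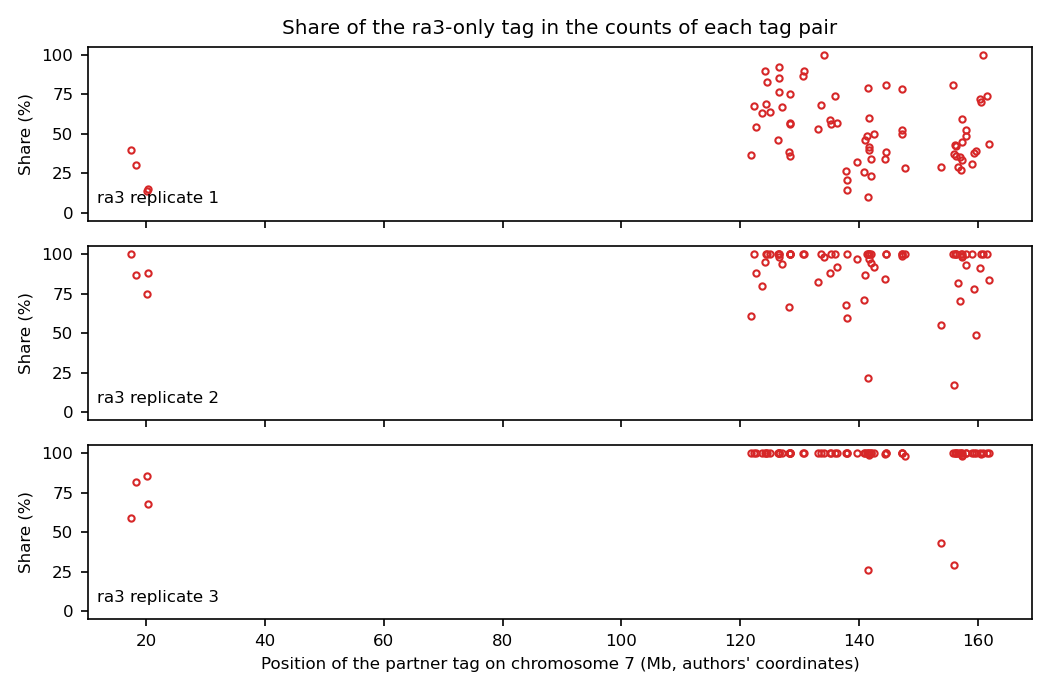
Share of the ra3-only tag in the summed counts of each tag pair (y axis, percent) against the position of the partner tag on chromosome 7 (x axis, Mb), 1 panel per ra3 replicate and 1 circle per pair, 75 pairs in all. From 121.8 to 147.8 Mb the median share is 56.2% in replicate 1 and 100% in replicates 2 and 3.

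The relative use of tags within a locus was compared to look for alternative 3′ ends. Among 6621 combinations of locus and enzyme, 6 passed the threshold, and 1 did so with the replicate block. The strongest was a DpnII pair on chromosome 7 at 160054377 to 160054731, where a tag had a log2 fold change of -7.10 and another 0.63. The falling tag was wild-type-only and lay in the segment from 153.8 Mb, so a changed sequence was not told apart from another 3′ end. On chromosome 1 at 291472743 to 291474121, an NlaIII tag had a log2 fold change of 7.48, and this tag was ra3-only. A further 2 lay on chromosome 5, at 152267737 and 192921425, and the others at 280894840 of chromosome 1 and 128390004 of chromosome 7. Of these, 192921425 lay in the chromosome 5 segment from 182.4 Mb, and 280894840 lay 0.025 Mb from a partner tag. The falling tag at 128390004 was the partner of a ra3-only tag (G12C), and the summed pair had a log2 fold change of 0.11, so this call did not show another 3′ end. The count was 1, 1 and 3 without wild-type replicates 2 and 3 and ra3 replicate 2, and 53 and 18 without ra3 replicates 1 and 3. Without wild-type replicate 1 edgeR called 0, with 62 at an unadjusted p under 0.05.

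The technical lanes of ra3 replicate 3 gave the spread between lanes described as technical replicates. Lanes 3 and 3b correlated across tags with r = 0.965 for DpnII and 0.975 for NlaIII tags, and their biological coefficient of variation was 0.0209 and 0.0221. Wild-type replicates had coefficients of 0.174 for DpnII and 0.238 for NlaIII tags, and ra3 replicates 0.297 and 0.550; ra3 replicates 1 and 2 alone had 0.289 and 0.226. A chi-square statistic per degree of freedom of 1.11 for both enzymes, near sampling noise, compared with 2.01 to 21.1 for pairs of biological replicates, so both lanes were counted as 1 sample. The NlaIII tags of ra3 replicate 3 stood apart from all other libraries, with a median r of 0.655 against the other replicates, where the other 5 replicates had 0.850 to 0.891. Their best match was wild-type replicate 3 (r = 0.770), above ra3 replicate 2 (r = 0.745). The DpnII tags of ra3 replicate 3 had a median r of 0.871, within the 0.840 to 0.894 of the others. Without these NlaIII tags, 74 loci and 568 tags passed the threshold.

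**Figure D4:**
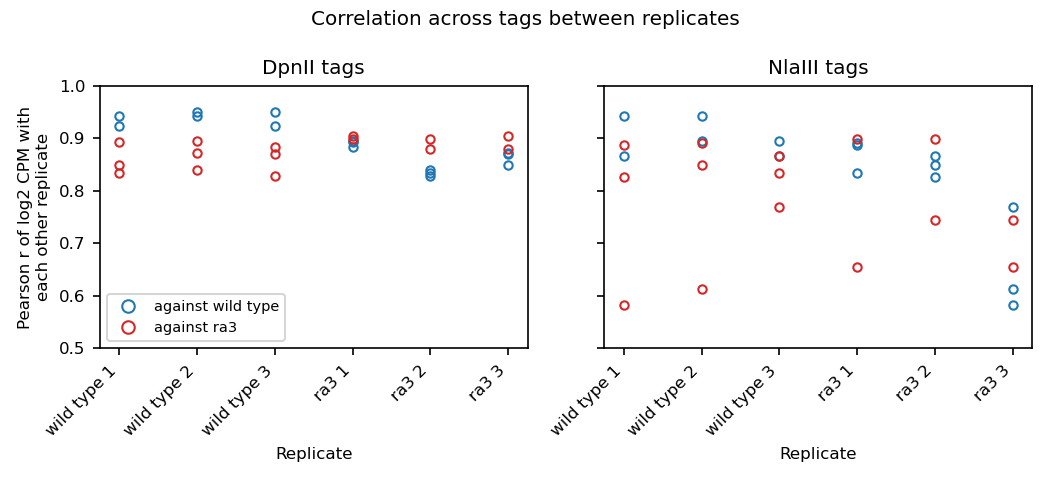
Pearson's r of log2 CPM across tags between each replicate (x axis) and each other replicate (circles, blue against wild type, red against ra3), for DpnII and NlaIII tags, with lane 3 standing for ra3 replicate 3. NlaIII tags of ra3 replicate 3 have a median r of 0.655, all other columns medians of at least 0.840.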

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

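The alternatives chosen after the data were seen were the other chaining distances, the ra3-only tags added to partner loci, the most abundant tag per locus, the fits without the NlaIII tags of ra3 replicate 3, the pairing check by enzyme, the tags of single named loci, and everything on ra3-only tags. The count of 35 loci was within 1.5 times under plain TMM, limma voom, the strict filter, DpnII tags alone, either lane of ra3 replicate 3, the replicate block (46), chaining within 2000 bp, the added ra3-only tags (31) and the most abundant tag. It was 120 with DESeq2, 448 without a filter, 12 with NlaIII tags alone, 22 with chaining within 500 bp, 74 without the NlaIII tags of ra3 replicate 3, and 9 to 206 when a replicate was left out. Of the 18 named loci, 11 passed with DpnII tags alone, 8 with NlaIII tags alone, 16 with limma voom and 8 to 18 when a replicate was left out. Over 334 refits of single named loci, 279 were on the same side of the threshold with the same sign and 54 fell short of it. The locus on chromosome 7 at 126449005 alone turned, to a log2 fold change of 0.75 once ra3-only tags were added to it, which adds counts in ra3 by construction. The odds ratio of chromosome 7 was 2.73 (exact p = 0.0540) with DpnII tags alone and passed under each other alternative, between 2.94 and 15 when a replicate was left out.

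Called tags numbered 637 with at least 10 counts in total and 203 to 701 when a replicate was left out, and stayed within 1.5 times elsewhere. Loci with changed tag use numbered 1 with the replicate block, 12 without the NlaIII tags of ra3 replicate 3 and 0 to 53 when a replicate was left out. With the block, 34 of the 35 loci and all 18 named loci were called, and no other count of calls moved by over 1.5 times. The correlation between enzymes ranged from 0.305 to 0.406 when a replicate was left out. Under the strict filter the lanes of ra3 replicate 3 correlated with r = 0.963 for DpnII and 0.975 for NlaIII tags. Of the ra3-only tags without a position, 246 were DpnII and 294 NlaIII tags, and the criteria gave 367 to 545 tags when a replicate was left out. Except where the construction is named, the cause of these shifts was not tested. At the simulated depth and spread, 16% of 2-fold changes of loci were recovered. The alternatives on the ra3 level, gene lists, antisense share, windows of 5 and 20 Mb and 3′-most annotated site were not run.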

Other observations

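Several of the most abundant tags of both genotypes lay on chromosome 1. The tag GATCGATGGATGCTGTTACC at 178338880 had 4192 ± 643 CPM in wild type and 2851 ± 494 CPM in ra3 (SD, n = 3), and the tag at 152232732 had 3532 ± 411 and 3160 ± 1281 CPM. The tag at 204545521 had 2515 ± 351 and 2393 ± 144 CPM. Outside the segments, 14 loci passed the threshold, 9 higher and 5 lower in ra3, and 5 of these 14 lay within 5 Mb of a partner tag. The locus gained on chromosome 6 at 16935473 and the locus lost there at 28419976 lay 148 and 136 Mb from the nearest partner.

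All tests in the next 3 paragraphs were chosen after the patterns had been seen. The 540 ra3-only tags without a genome position may be sequence variants of another maize line kept in the ra3 stock. As that idea needs, partner loci crowded together, with 21 in the fullest 10-Mb window and at most 7 in 95% of random draws. RNA of another organism added to the ra3 libraries would leave the partners at the level of matched tags. Their median log2 fold change minus that of placed tags matched in wild-type count was -2.23. RNA of another maize line could lower the tags that it lacks relative to shared ones, so this value cannot test that. B73 transcripts switched on in ra3 would not lower the partners either, and 95.3% of these were lower, against 46.7% of the matched tags. For ra3-only tags without a partner, B73 transcripts stay open: 8.63% of the 591 ra3-only tags had a position, but the authors' tables list no tag with more than 3 positions, so repeats would lack one too.

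The shares of ra3-only tags differed between the ra3 pools. Wild-type RNA mixed into replicate 1 would lower its share in every segment. The difference between segments (permutation p = 1e-05) cannot test this, because shares also differed between segments in replicates 2 and 3. The median share of replicate 1 was lowest on chromosome 7 and at 173.0 to 186.1 Mb of chromosome 2. In the other segments it was highest, as on chromosome 1 (50.5% against 26.3% and 37.1%) and chromosome 8 (81.7% against 58.0% and 58.5%). The chromosome 5 median covered a change of order. In most pairs there before 193880963 replicate 1 was highest, as at 182821519 (82.5% against 49.2% and 62.3%). From 193880963 on it was lowest in every pair, as at 194297118 (46.2% against 100% and 100%). This argues against mixing as the only cause. Mixing would also bring abundant wild-type transcripts into replicate 1. The lost locus on chromosome 6 at 28419976 had 338, 306 and 287 counts in wild type and 0 in ra3 replicate 1. The wild-type-only tag at 160964137 of chromosome 7 had 195, 174 and 173, and 0. All 23 wild-type-only tags, selected for low ra3 counts, had at most 2 in that replicate. These counts argue against mixing large enough to set the chromosome 7 shares. A trace was not tested. Expression that favours an allele gene by gene would vary the lowest pool from gene to gene, and replicate 1 was lowest in 96% of the chromosome 7 pairs. Donor segments still segregating among the pooled ears remain a candidate explanation, but the test left it open: segments took 38.5% of the variance in replicate 1, between the bounds set for and against it. Segments took 69.2% in replicate 2 and 77.7% in replicate 3, above the bound set for it, but the test was set on replicate 1. Without ra3 replicate 1, where the shares on chromosome 7 were lowest, the odds ratio of chromosome 7 was 15.

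The NlaIII tags of ra3 replicate 3 stood apart. A different RNA pool would also move its DpnII tags, but these had a median correlation 0.217 higher than its NlaIII tags. An error of 1 lane would separate lanes 3 and 3b, which correlated with r = 0.975 in NlaIII tags. More complete cutting by NlaIII in this library may account for it: relative to ra3 replicates 1 and 2, upstream NlaIII tags lay at a median of -1.13 (log2; quartiles -2.61 and 0.10) against the 3′-most tag of their locus over 4681 loci, and upstream DpnII tags at 0.02. A difference in NlaIII library preparation of another kind was not tested. The upstream comparison was not run for wild-type replicate 3, whose NlaIII deviations over loci correlated with those of ra3 replicate 3 (r = 0.359). Whether the pattern is confined to this library is therefore not known.

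Each of the 10 splits of the 6 replicates into 3 and 3 was fitted once. The real split gave 35 loci, 409 tags and 6 loci with changed tag use, it was the only 1 of the 10 to give as many of each, and the highest count among the other splits was 0 for each of them. This held for the 3 other splits that part all pairs of same-numbered replicates and for the 6 that part 1 pair. With 10 splits a share under 0.05 cannot be reached.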
